A study of Mus musculus with 7 samples.

How the data were processed

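The 7 libraries came from the mouse pre-B cell line B3: endogenous Ikaros ChIP (2 libraries), HA-Ikaros ChIP from transduced cells (2), wild-type input (2) and transduced input (1). The deposited files list aligned reads, 1 line per read, all 36 bp long, on chromosomes 1 to 19, X and Y. CASAVA 1.7 and build mm9 are named in the submitters' processing notes; the settings of the alignment are not given in the sources used here. The score column of the deposited files held 0 on every line and was not used. No file held 2 reads with the same chromosome, first base and strand, but paired libraries shared 5412858 such positions for endogenous ChIP, 638396 for HA-Ikaros ChIP and 4512362 for wild-type input.

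Files were read with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pyarrow 21.0.0. Strand cross-correlation on chromosome 1 peaked at 68 bp for both endogenous libraries and 92 bp for both HA libraries, and first bases were moved by 40 bp. Libraries of a group were compared by shared positions and by a chi-square of reads in 2 kb tiles. The pairs agreed within sampling noise and shared reads at identical positions, as lanes of 1 library would, so their reads were joined with 1 read per position and strand. Design and tests had been fixed before the data were examined, with limma-voom over 7 replicate libraries as the main fit. That fit needs replicates, so the main tests were replaced by tests on the reads of the 4 joined libraries, and limma-voom is given as an alternative. These tests were chosen after the data were examined. Nothing in the labels says that the libraries came from separate cultures, and p-values measure the counting of reads in these libraries.

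Reads were counted in 500 bp tiles of chromosomes 1 to 19 and X. Libraries were scaled by the trimmed mean of M values on 10 kb bins, which gave factors of 0.951, 0.976, 1.04 and 1.04 for endogenous ChIP, HA-Ikaros ChIP, wild-type input and transduced input. Tiles were kept where the scaled mean over the joined libraries was at least 1.5 times the median of tiles with reads. Each ChIP was compared with the input of the same cells by an exact conditional binomial test, 2-sided, the difference of the 2 enrichments by a likelihood-ratio test, and the inputs by the exact binomial test. P-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p of 0.05. Log2 enrichments were computed with 0.5 added to each count, and called tiles at most 500 bp apart were merged. The named regions were the 5 with the largest mean log2 enrichment among those called in both and at least 1 kb long, and in each direction the 3 with the largest difference among those called in 1 comparison and past the difference test.

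The tests were checked on simulated reads at the means of 925160 tiles, with 200 tiles changed. For endogenous Ikaros, 44.0% of tiles changed 4-fold and 100% of those changed 16-fold were recovered, for HA-Ikaros 13.0% and 100%, and for the difference 1.0% and 25.0%. The exact test called 2 unchanged tiles for endogenous Ikaros and 0 for HA-Ikaros. The simulated reads varied by sampling alone, which the exact test assumes, so few such calls followed from the setting. Further spread between libraries was not simulated, though the transduced and wild-type inputs differed at a chi-square per degree of freedom of 1.21. The false calls in the real data may thus be more. The likelihood-ratio test put 6.32% of unchanged tiles under an unadjusted 0.05 and 0.163% under 0.001, slightly more than its nominal level. For the difference, reads were raised in the HA-Ikaros ChIP alone, in tiles without enrichment in the other libraries. A 4-fold difference of this kind was rarely detectable at this depth. Differences higher for endogenous Ikaros, and differences at tiles enriched in both, were not simulated. limma 3.58.1 in R 4.3.3 was tested in the same way on 100000 tiles, where limma-voom recovered 62.0% of tiles changed 4-fold for endogenous Ikaros. Its 7 libraries were drawn independently, while the real pairs shared reads, so this recovery may not hold for them.

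Alternatives covered keeping every read of paired libraries, the scaling, the background, tile size, filter, threshold, read shift, high-input tiles, each library left out, limma-voom, limma-trend and a replicate block; limma-voom in this role, thinning to equal depth, leaving out tiles without input reads and the overlap against a pooled input were chosen after seeing the data. Coordinates are 1-based on mm9. The gene table at hand follows another assembly (GRCm38.p6), so gene names, promoters, gene lists, the place of regions in genes, the coding exons of Ikzf1 and sequence motifs were not analysed here. Figures were drawn with matplotlib 3.10.9.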

Results

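The series mapped where the transcription factor Ikaros sat on the genome of B3 cells, a mouse pre-B cell line. Ikaros, encoded by Ikzf1, is a zinc finger protein that regulates lymphocyte development. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done in 2 ways: in wild-type B3 cells with an antibody against the C-terminal part of Ikaros, and in B3 cells carrying a retroviral Ikaros with a haemagglutinin (HA) tag, with an antibody against the tag. Unprecipitated chromatin (input) of each kind of cell gave the background. The 7 deposited libraries were 2 of endogenous Ikaros ChIP (12760537 and 12725467 reads), 2 of HA-Ikaros ChIP (20217974 and 17970292), 2 of wild-type input (17403383 and 17530396) and 1 of HA-transduced input (11152868).

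The paired libraries of each group differed by less than the sampling noise and were counted as 1 sample. Over 2 kb tiles the chi-square per degree of freedom was 0.558 for the endogenous pair, 0.965 for the HA pair and 0.739 for the wild-type input pair, against 1.21 to 2.39 between libraries of different groups. They also shared reads with the same first base and strand on chromosomes 1 and 2: 42.4% of the smaller library for the endogenous pair, 25.7% for the wild-type input pair and 3.47% for the HA pair, where positions 1 to 3 bp apart gave 1.11%, 2.12% and 1.24%. Joined, they held 20073146, 37549870, 30421417 and 11152868 distinct reads for endogenous ChIP, HA-Ikaros ChIP, wild-type input and transduced input. Shared reads themselves lower the chi-square, so its values under 1 are no separate sign from the sharing. The evidence was weakest for the HA pair, whose sharing and chi-square lay closest to those of separate libraries, so counting it as 1 sample is less certain. Each group thus had n = 1, no difference below has a replicate check, and each test compares these libraries and not the conditions.

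The first comparison asked where endogenous Ikaros was enriched over the input of the same cells. Of 925160 tiles of 500 bp tested, 46624 (5.04%) held more ChIP reads and 1027 fewer, with a median log2 enrichment of 2.37 (quartiles 1.94 and 2.90) among those that were higher. They merged into 24930 regions that covered 24.8 Mb, with a median width of 500 bp and a widest region of 11500 bp. Regions lay most densely on chromosomes 11 (17.4 per Mb) and 19 (15.2 per Mb) and most thinly on chromosome X (2.75 per Mb), where the wild-type input itself held 0.370 times the reads per kb of the median autosome. The 1 Mb bin with the most regions of both antibodies, chromosome 17 from 29000001 to 30000000 (build mm9), held 71 endogenous and 47 HA-Ikaros regions. The test was an exact conditional binomial test per tile with Benjamini-Hochberg adjustment. Thinning every library to the depth of the transduced input left 19607 tiles. Keeping every read of the paired libraries gave 63143 higher and 6781 lower tiles, and limma-trend over the 7 libraries 113907 and 38276.

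The second comparison asked where tagged Ikaros was enriched over the input of the transduced cells. HA-Ikaros was higher at 22314 tiles (2.41%) and lower at 699, and the median log2 enrichment of the higher tiles was 2.69 (quartiles 2.22 and 3.28). These merged into 14177 regions over 11.8 Mb. Chromosomes 11 and 19 again held the most, at 9.63 and 9.37 regions per Mb, and chromosome X the fewest at 1.72 per Mb. The count was 46894 tiles with all 3 inputs taken as 1 background, which changes both the depth and the cells of the control, and 14720 with the other libraries thinned to the depth of the transduced input. With the 7 libraries treated as replicates, 9771 tiles were higher and 689 lower in limma-voom, and 53793 and 10531 in limma-trend.

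The tiles called with the 2 antibodies were then compared. Of the HA-Ikaros tiles, 80.2% (17885) were also called for endogenous Ikaros, against 1124.5 for independent lists, and 38.4% of the endogenous tiles were called for HA-Ikaros. By regions, 11790 HA-Ikaros regions (83.2%) shared at least 1 bp with an endogenous region. Of the 28739 tiles called for endogenous Ikaros alone, 86.0% had an HA-Ikaros log2 enrichment above 0, with a median of 1.06, where 39.0% did among tiles called in neither comparison. Across tested tiles, which are not independent replicates, the 2 log2 enrichments had Pearson's r of 0.31. Within tiles called in both r was 0.09, and within tiles called in either it was -0.017. These tiles were chosen on the same 2 enrichments, which by itself lowers r. The low values thus do not show that the enrichments were unrelated at called tiles. Around the midpoints of the 11817 regions called in both, the read density of the central bins was 6.40 times that of the flanks for endogenous Ikaros, 7.0 times for HA-Ikaros, 1.38 times for the wild-type input and 1.42 times for the transduced input. The regions were called on these same reads, so a ChIP peak over a flatter input follows from their choice and is no separate evidence. The overlap depended on depth, background and test: it was 8604 tiles at equal depth (58.5% of the HA-Ikaros and 43.9% of the endogenous tiles), 9086 in limma-voom (93.0% and 14.3%) and 32428 with 1 pooled input (69.2% and 63.2%).

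**Figure D1:**
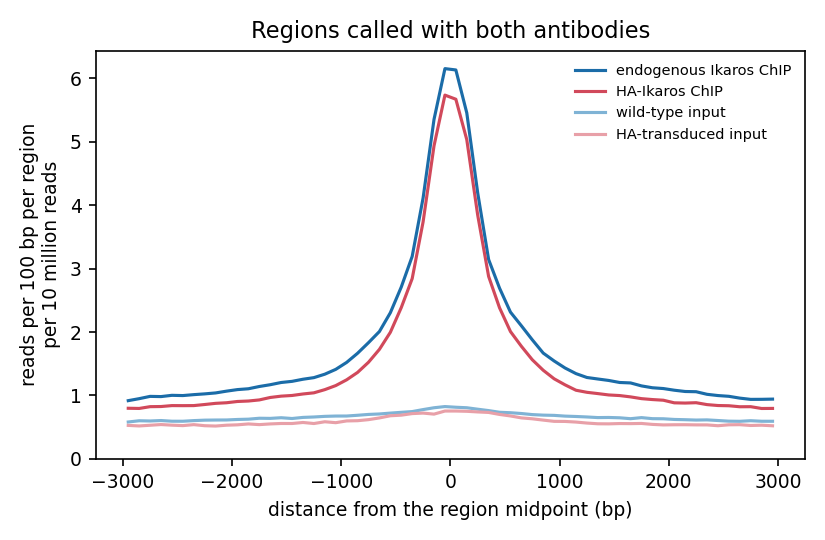
Reads per 100 bp and region, scaled to equal library size (y axis) against the distance in bp from the midpoint of the 11817 regions called with both antibodies (x axis), 1 line per joined library. The centre stands 6.40 times over the flanks for endogenous Ikaros and 7.0 times for HA-Ikaros, and under 1.5 times for the inputs. The regions were called on these same reads, which favours this shape.

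**Figure D2:**
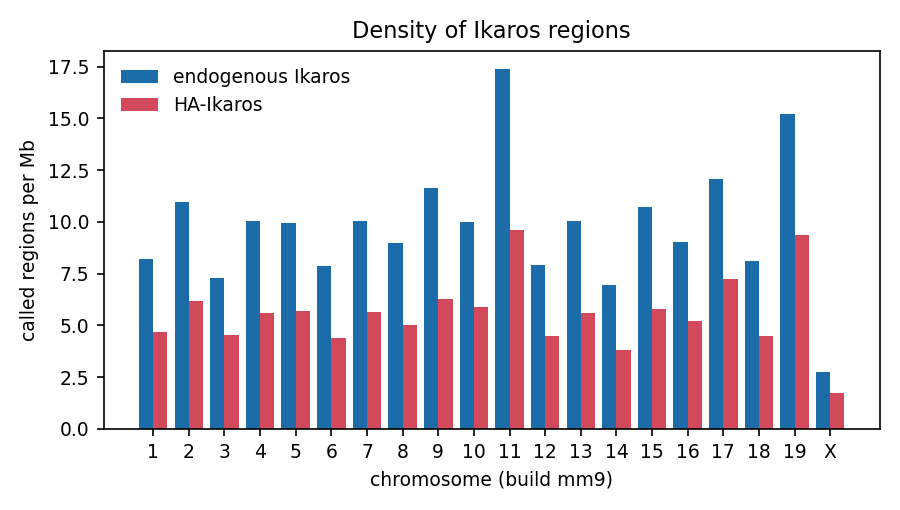
Called regions per Mb (y axis, from 0) on each chromosome of build mm9 (x axis), with 1 bar per antibody and no error bars, since each group is 1 sample. Chromosome 11 stands highest for endogenous Ikaros at 17.4 per Mb and chromosome X lowest at 2.75 per Mb.

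The rule for named regions was set before the data were examined, but the calls and the difference test that it uses were chosen afterwards. The strongest region called in both lay on chromosome X from 58437001 to 58439500: endogenous ChIP held 321 reads against 4 of wild-type input, a 132-fold enrichment (95% exact counting interval 51.2 to 489), and HA-Ikaros ChIP held 563 against 2, an 89.1-fold enrichment (24.6 to 738). On chromosome 14 from 34002501 to 34003500, endogenous Ikaros was enriched 19.2-fold (13.3 to 28.6) and HA-Ikaros 43.3-fold (16.8 to 159). On chromosome X from 39421001 to 39422000 the folds were 44.3 (19.9 to 122) and 20.4 (6.87 to 99.6). The transduced input held 0 reads in the other regions of this set. On chromosome X from 13153501 to 13154500, HA-Ikaros was at least 12.1-fold higher, with 115 reads, and endogenous Ikaros 12.4-fold (5.26 to 35.5). On chromosome 9 from 92279001 to 92280000, HA-Ikaros was at least 13.2-fold higher, with 125 reads, and endogenous Ikaros 9.99-fold (6.03 to 17.5). Against the pooled input, the HA-Ikaros log2 enrichments of the 3 regions with reads of transduced input were 6.67, 4.18 and 4.58 in the order given (6.16, 5.27 and 4.13 against that input), and those of the other regions were 4.39 and 2.997. Against the pooled input, HA-Ikaros on chromosome 9 thus lay below its stated minimum of 13.2-fold. Intervals and lower bounds, set at 3 reads for a library at 0, cover counting error only, and not the choice of regions by their enrichment.

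The third comparison tested the difference between the 2 enrichments. It was higher for HA-Ikaros at 105 tiles and for endogenous Ikaros at 716, by a likelihood-ratio test with Benjamini-Hochberg adjustment. Of these tiles, 61 and 315 also differed in the same direction when reads of the 2 ChIP libraries were compared with each other by the exact binomial test. The test also uses the input reads: the 105 tiles held a median of 20 wild-type and 1 transduced input reads, and the 716 tiles a median of 6 and 12, where all tested tiles held 11 and 4. Over all tested tiles the median log2 difference was -0.33, with medians of 0.19 for endogenous Ikaros and -0.19 for HA-Ikaros. In this processing the tested tiles as a whole thus lay toward endogenous Ikaros, but scaling by median ratios moved the median difference by 0.23. The constant added to each count before the log2 also weighs more on the transduced input, which held fewer reads, and so lowers the HA-Ikaros values. How much of the lean comes from these choices was not measured. The uneven split of the calls thus cannot be read as particular to these sites. The 3 tiles with the largest difference among those called for HA-Ikaros alone were on chromosome 7 from 120061501 to 120062000 (50 HA-Ikaros and 2 endogenous ChIP reads), chromosome 11 from 80319001 to 80319500 (59 and 3) and chromosome 5 from 102695501 to 102696000 (29 and 3). In all 3 the transduced input held 0 reads, so that HA-Ikaros was at least 5.28-fold, 6.23-fold and 3.06-fold higher than its input. The 3 called for endogenous Ikaros alone were on chromosome 9 from 58072501 to 58073000 (14 endogenous and 9 HA-Ikaros ChIP reads), chromosome 4 from 49085501 to 49086000 (11 and 4) and chromosome 8 from 59991001 to 59991500 (14 and 6). There the wild-type input held 0 reads and the transduced input 12, 6 and 6, and endogenous Ikaros was at least 7.70-fold, 6.05-fold and 7.70-fold higher than its input. Against the pooled input the log2 enrichments were 1.07 to 3.04 in the 3 tiles called for HA-Ikaros and 1.39 to 2.33 in the 3 called for endogenous Ikaros. These lay below the stated minima on chromosome 5 and in all 3 tiles called for endogenous Ikaros, though that background mixes the 2 kinds of cells. The tiles were picked for a large difference, and the minima do not allow for that choice. The calls on chromosomes 5, 9 and 4 did not pass the adjusted threshold against the pooled input; that on chromosome 5 was also lost with unmoved reads or either HA-Ikaros library left out, and that on chromosome 4 without endogenous library 2. Scaling by median ratios gave 166 and 402 tiles in place of 105 and 716. Leaving out wild-type input library 1 or 2 gave 72 and 396 or 94 and 438 (468 or 532 tiles in all). Without endogenous library 1 or 2 the counts were 62 and 712 or 48 and 573. Without HA-Ikaros library 1 or 2 they were 100 and 469 or 99 and 485. Tiles of 250 bp gave 14 and 455, and tiles of 1000 bp gave 217 and 886. With every read of the paired libraries kept, 425 and 1370 tiles differed, and in limma-voom over the 7 libraries 13 and 757.

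The inputs were compared as a check of the background. The transduced input was higher than the wild-type input at 622 tiles and lower at 1, by the exact binomial test with Benjamini-Hochberg adjustment. Tested tiles held a median of 4 transduced and 11 wild-type input reads, so a lower tile was much harder to call than a higher one. At an unadjusted 0.05 of the same test, 28197 tiles were higher and 11890 lower. The split of 622 to 1 is thus no measure of a one-sided gain. Leaving out wild-type input library 1 or 2 brought both directions together to 224 or 218. In limma-trend over the 7 libraries 9083 tiles were higher and 11100 lower. At the 36341 tiles where both ChIP libraries reached at least 5 times their median, the wild-type input held 2.25 times and the transduced input 2.47 times the reads of the other tiles. Over 2516 bins of 1 Mb, the log2 ratio of transduced to wild-type input had an SD of 0.127, against 0.0229 between the wild-type input libraries. Those 2 libraries shared reads and were counted as 1 sample, so 0.0229 holds no spread between separately made libraries. The 2 SDs thus do not show how far the cultures differed. Chromosome 8 had the lowest median of all chromosomes at -0.11, and chromosome 12 the highest at 0.10. The lowest bin was on chromosome 12 from 115000001 to 116000000, at -0.46, and 3 bins were at least 0.5 above.

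Within a window on chromosome 11 from 11550001 to 11720000, chosen after its values were seen, the transduced input exceeded the wild-type input in 5 short blocks between 11607751 and 11669500. The blocks held 172 transduced and 52 wild-type input reads, an 8.99-fold ratio with no test of its own, since the blocks were marked for this difference on the same reads. They were the tiles, of 680 of 250 bp in the window, that passed the exact binomial test with Benjamini-Hochberg adjustment. The largest block, from 11668751 to 11669500, held 101 transduced and 28 wild-type input reads.

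**Figure D3:**
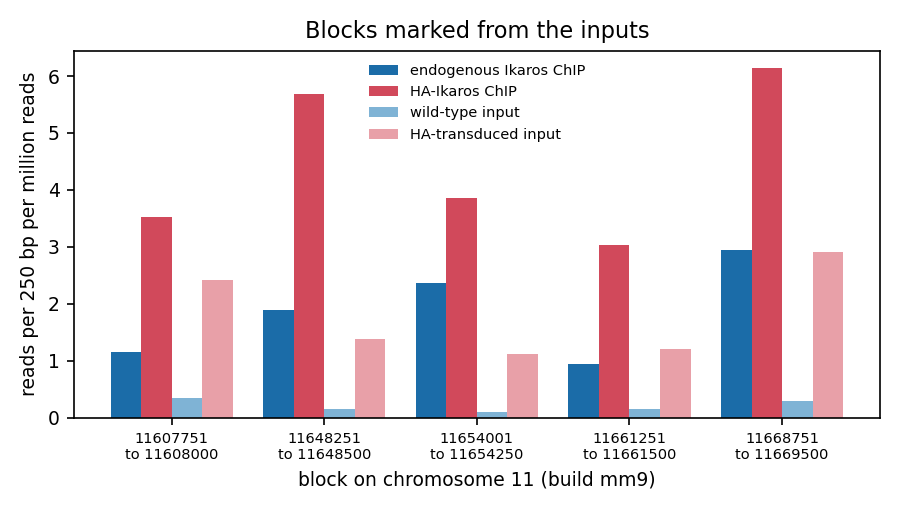
Reads per 250 bp, scaled to equal library size (y axis, from 0) in the 5 blocks on chromosome 11 of build mm9 that were marked from the inputs alone (x axis), with 1 bar per joined library. The wild-type input stands lowest in every block, as the marking favours.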

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

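The tests of explanations in this part were chosen after the results were seen. For the blocks on chromosome 11 they replaced earlier forms: the shape was first read from reads in the 250 bp beside the blocks (1.43 times those between, 1.09 to 1.85), then from the tiles beside whole blocks (0.321 of the highest tile, 5 of 10000 draws as low), which is not how the peaks were measured. The limit of 1.5 times for DNA without introns was first applied to the value and then to its whole interval. The first chromosome 8 test used endogenous ChIP over wild-type input (-0.03, SD 0.03) and left the question open.

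The difference between the enrichments passed its test at 105 tiles higher for HA-Ikaros and 716 higher for endogenous Ikaros in the joined libraries. These results stand here because the same contrast gave different values with the 2 antibodies; with n = 1 per group the test compares libraries and not conditions.

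The endogenous Ikaros ChIP, labelled as wild-type, held 9.58 times as many reads per tile in the blocks on chromosome 11 as between them (95% exact interval 8.37 to 10.9), where the transduced input held 15.4 times, HA-Ikaros ChIP 29.9 times (2.32-fold over the transduced input, 1.98 to 2.74) and the wild-type input 1.34 times. A library from transduced cells is argued against by chromosome 8, whose log2 ratio of HA-Ikaros to endogenous ChIP lay at -0.13 relative to the other chromosomes (SD 0.03), as between the inputs (-0.12). Over 1 Mb bins of all chromosomes the 2 ratios had Pearson's r of 0.81. Not every chromosome followed: the median of chromosome 12 was 0.10 between the inputs and 0.03 between the ChIP libraries. Ikaros bound at these places and DNA without introns, which a vector with an Ikaros coding sequence would bring, cannot be told apart. Whether the blocks are exons of Ikzf1 was not analysed here, so such a vector is named as a possibility only. Tiles next to the highest held 0.756 of its reads, and 4413 of 10000 draws of called peaks of like height went as low. That share cannot decide, since at least 1 such tile lies inside the largest block and the transduced input gave 0.722 too. In the 4 blocks of 1 tile the share was 0.405, and 47 of 10000 draws went as low. Reads of the endogenous ChIP were thus narrower there than at most peaks drawn, near the 0.366 of the transduced input, but this rests on 4 blocks of 1 library. The 250 bp beside the blocks held 1.43 times the reads between them, with an interval to both sides of the limit of 1.5, which the transduced input (2.19) and HA-Ikaros ChIP (3.13) themselves exceeded.

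Chromosome Y, which no comparison used, held 0.129% of the transduced input reads (Wilson interval 0.127 to 0.131) and 0.0988% of the HA-Ikaros ChIP, against 0.0224% of the wild-type input and 0.0217% of the endogenous ChIP. Loss of the chromosome from the wild-type culture is argued against by its first 800 kb, where the wild-type libraries held 0.898 times the reads of the transduced ones per read sequenced (0.861 to 0.936). In the rest of the chromosome the transduced libraries held 7.12 times as many, but 2.48 times without the stretch from 2700001 on: 100 kb from 2800001 held 21963 of the 46763 transduced reads at a ratio of 113, 4 of 21 bins of 100 kb exceeded 3 times the ratio of the first part, and 7 lay under 1.5. Reads of repeated sequence kept in 1 set of alignments and not in the other may give such uneven ratios; a gain of these stretches in the transduced culture was not tested. Another 64 bins of 10 kb in 19 runs, the longest on chromosome 8 from 127520001 to 127690000, each held at most 2 reads in the wild-type libraries while the transduced ones stood at 1.09 times their genome median, and 0 bins showed the reverse; for these bins, deletions in the wild-type culture and the handling of repeated sequence cannot be told apart, since both leave normal depth in the transduced cells and the sequence was not analysed here.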

How the results depend on the processing

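All 128 values computed for the 11 named regions under 11 settings that change their comparison kept their direction, and 121 their side of the adjusted threshold. The other 7 were in 3 of the tiles called in 1 comparison. These regions were picked for large values, so a kept direction is a weak check. Of 21 alternatives, 18 left the endogenous tiles within 1.5 times of 46624; 13 of 18 did for the 22314 HA-Ikaros tiles, 17 of 23 for the overlap of 17885, 12 of 22 for the difference (821) and 8 of 16 for the inputs (623). Pooling all 3 inputs gave 46894 HA-Ikaros tiles, 11917 differing tiles, then ChIP against ChIP, and an overlap of 32428, chosen after seeing the data, against 2599.9 for independent lists; a simulation without effects called 0 tiles and cannot show how much the shared input brings. Keeping every read of paired libraries raised the difference to 1795. With 250 bp tiles the difference fell to 469 and the inputs to 342; with the filter at 2 times the median the difference rose to 1394, and with all tiles of a mean of at least 1 read it fell to 366 and the inputs to 349. Without tiles of high input the inputs differed at 287. At equal depth, an alternative chosen after seeing the data, the counts were 19607, 14720, 8604 for the overlap, 131 for the difference and 148 for the inputs. Counting regions in place of tiles gave an overlap of 11790. Single libraries left out gave 468 to 774 tiles for the difference, lowest without wild-type input 1 (532 without 2), and 218 to 224 for the inputs without wild-type input 2 or 1. Total-read scaling moved the median log2 enrichment of endogenous Ikaros by -0.12 and median ratios by -0.16, and median ratios that of the difference by 0.23.

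Treating the 7 libraries as replicates, limma-voom called 9771 HA-Ikaros tiles, an overlap of 9086, 202 tiles between inputs, and 13 higher and 757 lower for the difference; limma-trend called 113907 endogenous and 53793 HA-Ikaros tiles, an overlap of 38369, 27686 for the difference (9682 higher, 18004 lower) and 20183 between inputs (9083 higher, 11100 lower). With a replicate block, limma-voom called 86794 endogenous tiles, 39609 HA-Ikaros tiles against wild-type input, an overlap of 33363 and 66714 for ChIP against ChIP (8588 higher for HA-Ikaros, 58126 lower); without the block, the same libraries gave 33424, 38838, and 3058 higher and 12881 lower. The replicate numbers share only a number: deviations of same-numbered libraries correlated at -0.00032, -0.00016 and 0.00061. Libraries of a group share reads, which lowers the spread these fits see; other causes were not tested. The chromosome 8 ratio of the inputs moved from -0.108 to -0.101 with total-read scaling and spanned -0.113 to -0.106 with a wild-type library left out. Alternatives for promoters, motifs, gene lists and locations were not run, since those results were not made.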

Other observations

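The test in this part was chosen after the result was seen. On chromosome 12 from 114700001 to 115150000, nearly all reads were missing in every library. The 450 kb held 62 reads over the 4 joined libraries, 0.213% of the level of the 700 kb before it: 14 of endogenous ChIP, 27 of HA-Ikaros ChIP, 16 of wild-type input and 5 of transduced input. The 52 tiles with reads held a median of 0.0526 times the genome median, with at most 3 reads in a tile, which is too few to test for sequence in which 36 bp reads cannot be placed. The immunoglobulin heavy chain locus lies on distal chromosome 12 and loses DNA when B cells rearrange it, so a loss of this stretch on both copies in the culture, with a few cells or stray reads left, may be the source; the 2 explanations cannot be told apart, since where reads can be placed was not measured and the design holds no group that tests a loss.

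The same part of the chromosome also differed between the cultures. The bin from 115000001 to 116000000 was the lowest of all 1 Mb bins between the inputs (-0.46 on the log2 scale) and was at -0.56 between the ChIP libraries, and the next bin lay at -0.42 in both. Over 1 Mb bins, which are not independent replicates, the ratios between inputs and between ChIP libraries had Pearson's r of 0.81.

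The highest 1 Mb bin between the inputs, chromosome 17 from 39000001 to 40000000, was 0.89 higher in the transduced input on the log2 scale, while HA-Ikaros ChIP lay at -0.64 against endogenous ChIP.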
